A study of Mus musculus with 51 samples.

How the data were processed

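The deposited values were log2 expression per probe set, which per the submitters' processing notes came from affy with RMA, for which no versions were given. Their range, from 1.94 to 14.7, lies on such a log2 scale, and array means lay within 5.71 to 5.79. The raw array files were not at hand, so background correction and summarization were taken as deposited, and the genome build is not stated. The values were used without further normalization. Of 45101 probe sets, 64 were controls, 34958 carried 1 gene symbol, 932 several and 9211 none, and 34754 of the named ones matched the gene table by gene identifier. For each of 18194 genes, the probe set with the highest mean over all arrays was tested.

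Group means were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over the 51 arrays, moderated variances (34 residual degrees of freedom) and a two-sided Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons, the gene lists, the rule for named genes and all alternatives not listed here as later were chosen before the data were examined. SE is that of the limma fit, and block SE that of the fit with the replicate number of each clone as a block (16 residual degrees of freedom). That fit serves as an alternative, because the labels do not say whether equal numbers mark parallel cultures. Numbers were taken to pair where every same-numbered uninduced and induced array correlated above 0.1 across genes after subtracting group means. This held in 6 clones and not in AIREdel, where the lowest r was 0.0984, or SUMF1, where it was -0.321. In SUMF1 uninduced replicate 1 correlated with induced replicate 3 (0.597), 3 with 1 (0.585) and 2 with 2 (0.645). The block fit kept the numbers as given, so neither its 0 calls in SUMF1 nor its pooled variance allows for this. No parental cells without tetracycline were profiled, so the effect of the drug's removal was separated from a clone's own response only by subtracting the mean of the other 7 clones. For MYC this step also set 17 h without the drug against 24 h.

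Named genes were, for each induction and for both means, the 10 largest rises and 10 largest falls past the adjusted p whose arrays did not overlap between groups, or, for the means, that had 1 sign in every clone. For genes called with the block this rule was departed from after the data were seen: 1 direction in all 3 pairs took the place of no overlap. By this, Cdc42ep2 in GTF2IRD1 and Stk31, Sirt5, Glb1, Ntpcr, Egfl6, Pla2g7, Epas1, H1f2 and Mlana in MYC were named although their arrays overlapped. For each clone minus the other 7, or minus EB3, they were the 5 largest rises and 5 largest falls past the adjusted p. The targeted genes, and up to 4 members per list with the largest change, were added, and probe sets with several symbols or none were not named. Adm, Umps and Tfeb lie outside this rule and were named after their values were seen. Members of lists that did not pass, and these 3 genes, were not recomputed under the alternatives.

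The 27 lists were tested with limma's camera at a preset correlation of 0.01, two-sided, in the 8 inductions, their mean and the mean against EB3, 270 tests adjusted together. Of these 31 passed: 20 in single clones, 6 in the mean induction effect and 5 against EB3. With a correlation estimated from the data 0 passed after adjustment and 8 had an unadjusted p under 0.05. Of the 270 tests fry, which tests whether a list moves on balance, called 5, and it kept 3 of the 31. With the block, 41 passed in the 9 induction comparisons, and 0 of these with an estimated correlation. Tests on 8 clone values were exact sign-flip tests, two-sided, whose smallest possible p is 0.00781.

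The code was tested on simulated data. In each simulated set 50 genes were changed by each of several known sizes, from 1.41-fold to 4-fold, all at once among unchanged genes. For a 1.41-fold change the unblocked fit recovered 31 of 50 in GTF2IRD1 and 29 of 50 in MYC, and the block fit 37 and 40. For unchanged genes, 2.22% had a p under 0.05 without the block and 5.01% with it in the GTF2IRD1 comparison, so the unblocked test was conservative where pairs vary together. The share of false calls, among the calls of all sizes together, was 0.0165 and 0.0603 in that comparison, and 0.0113 and 0.0686 in the MYC comparison.

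The alternatives were a filter on dim genes, quantile normalization, median centring, limma's trend and robust options, array weights, every named probe set, an added 1.5-fold threshold, the arrays of the compared groups alone, the replicate block and leaving out each array in turn. Alternatives chosen after seeing the data were a block in only the 6 clones whose numbers pair, the block combined with each other alternative, induced arrays against EB3, the similarity of clones without each array, and the count of targeted genes under each alternative.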

Results

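The series profiled mouse embryonic stem cells in which 1 transgene at a time is held off by tetracycline and comes on when the drug is withdrawn. The parental line EBRTcH3, called EB3 here, was kept in tetracycline and gave 3 arrays. The 8 clones were AIREdel, titled as a deleted isoform of AIRE, BRWD1, GTF2I, GTF2IRD1, GTF2IRD2, MYC, SUMF1 and WBSCR1, each with 3 uninduced arrays in tetracycline and 3 induced arrays after 24 h without it, or after 17 h for the MYC clone. The design text calls the 3 arrays of a group biological replicates. In all, 51 arrays fell into 17 groups, and their number limits the precision of every value. Mean log2 signal per array lay between 5.71 and 5.79, and each array correlated with the rest of its group at a median r of 0.989 to 0.997 across probe sets. Signs of RNA quality did not move with induction over the 8 clones: the log2 gap between 3' and 5' control probe sets differed by a mean of -0.01 for Gapdh (exact sign-flip p = 0.320). It differed by 0.01 for beta-actin (exact sign-flip p = 0.422).

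The gene that each clone is named for was read first, since its level checks the labels. Across the 22 probe sets of these 8 mouse genes, 0 rose past the limma adjusted p in their own clone, 1 fell, and 10 lay above 0. The largest positive difference was that of Aire, the thymic regulator of self-antigen expression, at 8.26 ± 0.13 induced and 7.95 ± 0.20 uninduced (SD, n = 3 each), a log2 difference of 0.31 (SE 0.39). Eif4h, the mouse gene whose older symbol is Wbscr1, stood at 12.27 ± 0.31 and 12.19 ± 0.08, a difference of 0.08 (SE 0.11). Gtf2ird2 differed by 0.14 (SE 0.16), Sumf1 by -0.00 (SE 0.21), Myc by -0.05 (SE 0.21) and Brwd1 by -0.08 (SE 0.20). Gtf2i differed by 0.03 (SE 0.17) in its brightest probe set and by -0.44 (SE 0.18), -0.51 (SE 0.20) and -0.27 (SE 0.19) in 3 further ones, none past the adjusted p with or without the block. The sources used here do not give the sequence or species of the constructs, nor what the deleted isoform lacks, and a probe set outside the transgene checks nothing, so these values do not show whether a transgene came on.

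Gtf2ird1 and Ttc32 fell after induction of the GTF2IRD1 clone. Gtf2ird1, which encodes a transcription factor of the TFII-I family, dropped from 9.36 ± 0.06 to 7.75 ± 0.24 (SD, n = 3 each), a log2 difference of -1.61 (SE 0.13, limma adjusted p = 2.62e-11). Ttc32, a gene for a protein with tetratricopeptide repeats, dropped from 8.08 ± 0.31 to 6.34 ± 0.19, a log2 difference of -1.74 (SE 0.14, limma adjusted p = 2.62e-11). All 3 induced arrays lay below all 3 uninduced arrays for both genes. The mean difference of the other 7 clones was -0.05 for Gtf2ird1 and 0.01 for Ttc32. These were the 2 genes past the adjusted p out of 18194 tested, and 4 passed without GTF2IRD1 induced replicate 2. A further Gtf2ird1 probe set differed by -0.69 (SE 0.14, adjusted p = 0.130), and passed with the replicate number as a block (adjusted p = 0.0186). A dim Ttc32 probe set, at a mean level of 4.90, differed by -0.23 (SE 0.11).

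**Figure D1:**
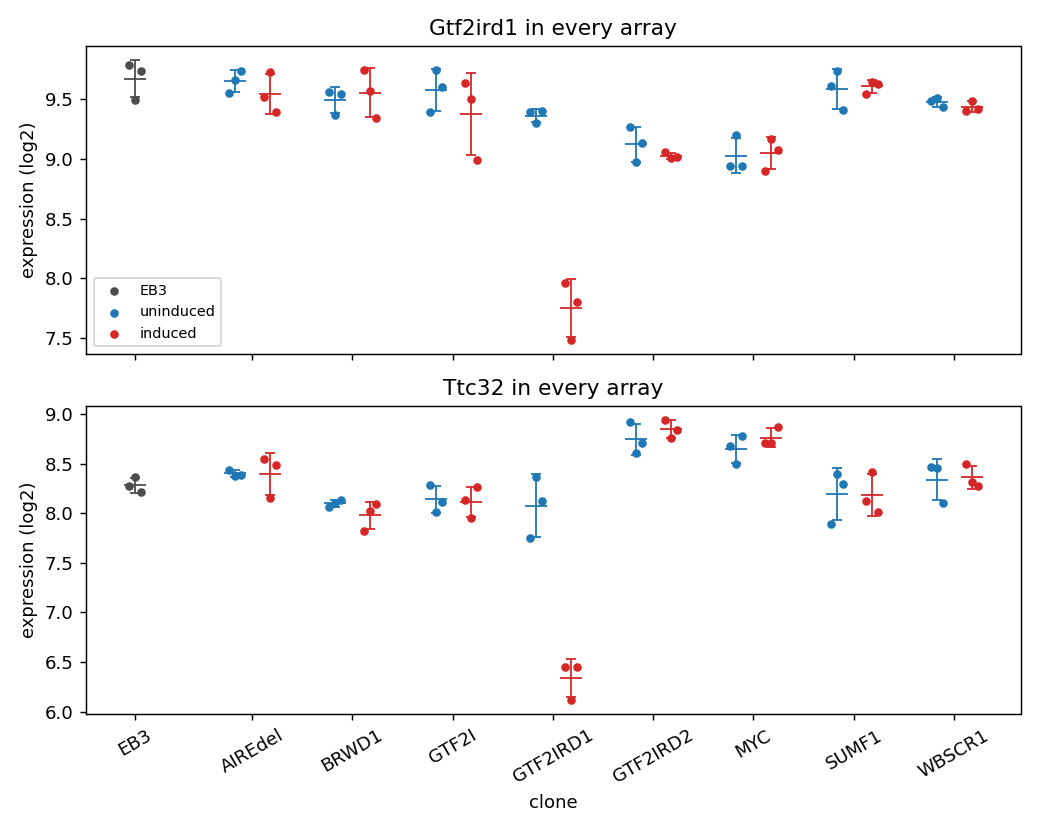
Log2 expression of Gtf2ird1 (upper panel) and Ttc32 (lower panel) in every array by clone, with 1 point per array, horizontal bars for group means and error bars for 1 SD (n = 3). The 3 induced arrays of the GTF2IRD1 clone, with means of 7.75 and 6.34, lie below all other arrays for both genes.

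Same-numbered uninduced and induced arrays deviated together in the GTF2IRD1 clone, at r of 0.209 to 0.655 across genes. Uninduced replicate 3 correlated more with induced replicate 1 (0.272) than with its own number (0.209), so the numbers only partly mark pairs here. With the replicate number as a block the call widened to 13 genes, 3 higher and 10 lower. Tgfbi, a secreted matrix protein, rose by 0.67 (block SE 0.11), Cdc42ep2, a Cdc42 effector, by 0.75 (block SE 0.10) and Glod5 by 0.76 (block SE 0.13). Among the falls were Gm20767 at -2.58 (block SE 0.48, of uncertain size at a dim 3.54 when induced), Eprn at -0.75 (block SE 0.11) and the synaptonemal complex gene Sycp3 at -0.72 (block SE 0.14). The zinc finger gene Trps1 fell too, at -0.69 (block SE 0.13), as did 1190005I06Rik at -0.64 (block SE 0.12), Chmp4c at -0.60 (block SE 0.11), Mcf2 at -0.56 (block SE 0.09) and the cell adhesion gene Emb at -0.42 (block SE 0.07). With a block in only the 6 clones whose numbers pair, an alternative chosen after seeing the data, 7 of the 13 genes passed, and without pair 1, 2 or 3 the block fit called 5, 4 or 6 genes. Naive pluripotency genes lay lower on balance in this clone, with a mean of -0.09 over 28 measured members, 10 of them above 0 (camera adjusted p = 0.00243, and adjusted p = 0.246 with an estimated correlation). Fbxo15 at -0.325 (block SE 0.07) and Tbx3 at -0.33 (block SE 0.10) were the 2 members that fell with the block when adjusted over the list alone, against 0 over all genes. Of the 28 genes of the 2-cell-like list 18, among them the Zscan4 genes and Dux, were not measured, and the other 10 had a mean of -0.56 and a median of -0.17 (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Gm20767 and AF067061, at -1.87 (block SE 0.42), both fell with the block when adjusted over the list alone, and made up most of that mean.

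Further list tests in the GTF2IRD1 clone concerned hypoxia and stress. Hypoxia and glycolysis genes had a mean of 0.15 over 30 measured members, 24 above 0 (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Egln3 at 0.695 (block SE 0.185), Ankrd37 at 0.55 (block SE 0.14) and Adm at 0.41 (block SE 0.13) were the 3 members that rose with the block when adjusted over the list alone, against 0 over all genes. Genes of the integrated stress response had a mean of -0.09 over 33 measured members (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. With only the brighter genes the hypoxia (0.243) and 2-cell-like (0.0736) calls ended. The pluripotency call ended without induced replicate 3 (0.0508), and the 2-cell-like call without uninduced replicate 2 (0.342), induced replicate 1 (0.132) or induced replicate 3 (0.147). The hypoxia call ended without uninduced replicate 2 (0.0568), induced replicate 1 (0.802) or induced replicate 3 (0.576), and the stress call without uninduced replicate 3 (0.288) or induced replicate 2 (0.700).

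In the MYC clone, 0 genes passed the limma adjusted p without a block, with 517 at an unadjusted p under 0.05 (2 genes passed without uninduced replicate 1 or induced replicate 3, and 1 without induced replicate 1). Its same-numbered arrays deviated together more than in any other clone, at r of 0.725 to 0.861 across genes, and with the block 65 genes passed, 27 higher and 38 lower. Among the falls were Myl9, a myosin light chain, at -1.35 (block SE 0.20), and Vcl, which encodes vinculin, at -0.65 (block SE 0.08, blocked limma adjusted p = 6.07e-04). The 3 Myl9 pairs stood at -2.32, -1.13 and -0.59, a spread that the block SE, which rests on all clones, does not measure. Cald1, which encodes caldesmon, stood at -0.57 and the focal adhesion gene Lpp at -0.56. Further falls were Skor1 at -1.28 (block SE 0.19), Insm1 at -0.94 (block SE 0.20), the hypoxia-inducible factor Epas1 at -0.70 (block SE 0.13) and the homeobox gene Meis2 at -0.63. So were Rprd2 at -0.79, Egfl6 at -0.76, Pla2g7 at -0.73, the linker histone H1f2 at -0.67, Mlana at -0.67 and the stress gene Ddit3 at -0.58. Among the rises were Fkbp11, a peptidyl-prolyl isomerase of the endoplasmic reticulum, at 0.68 (block SE 0.10), and Cpeb1, a regulator of polyadenylation, at 0.69 (block SE 0.11). Cpeb1, at 3.48 uninduced and 4.17 induced, and Egfl6, at 4.38 and 3.63, were dim, below the median array level of 5.11, which leaves the size of their change uncertain, as it does for Insm1 (4.56), Mlana (4.85) and Meis2 (4.65), which lay below it when induced. Further rises were Slc39a11 at 0.61, Stk31 at 0.60, the recombination gene Rad51b at 0.59, the deacylase gene Sirt5 at 0.58, Lingo3 at 0.55, the lysosomal enzyme gene Glb1 at 0.54, Ccdc40 at 0.54 and Ntpcr at 0.51. Cald1, Lpp, Meis2 and Ddit3 lie outside the fixed naming rule and were named after their values were seen.

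The count of 65 was fragile. With a block in only the 6 clones whose numbers pair, 13 of the 65 genes passed, 2 higher and 11 lower: Cpeb1 and Fkbp11 among the rises, and Vcl, Meis2, Ddit3, Gpc4, Commd3, Rprd2, Epas1, Rbm14, Skor1, Ctxn3 and Myl9 among the falls. The 6 arrays of the MYC clone alone, with the block, gave 8 genes, 5 of them among the 65. Without pair 1, 2 or 3 of the MYC clone the block fit called 21, 1 or 6 genes.

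**Figure D2:**
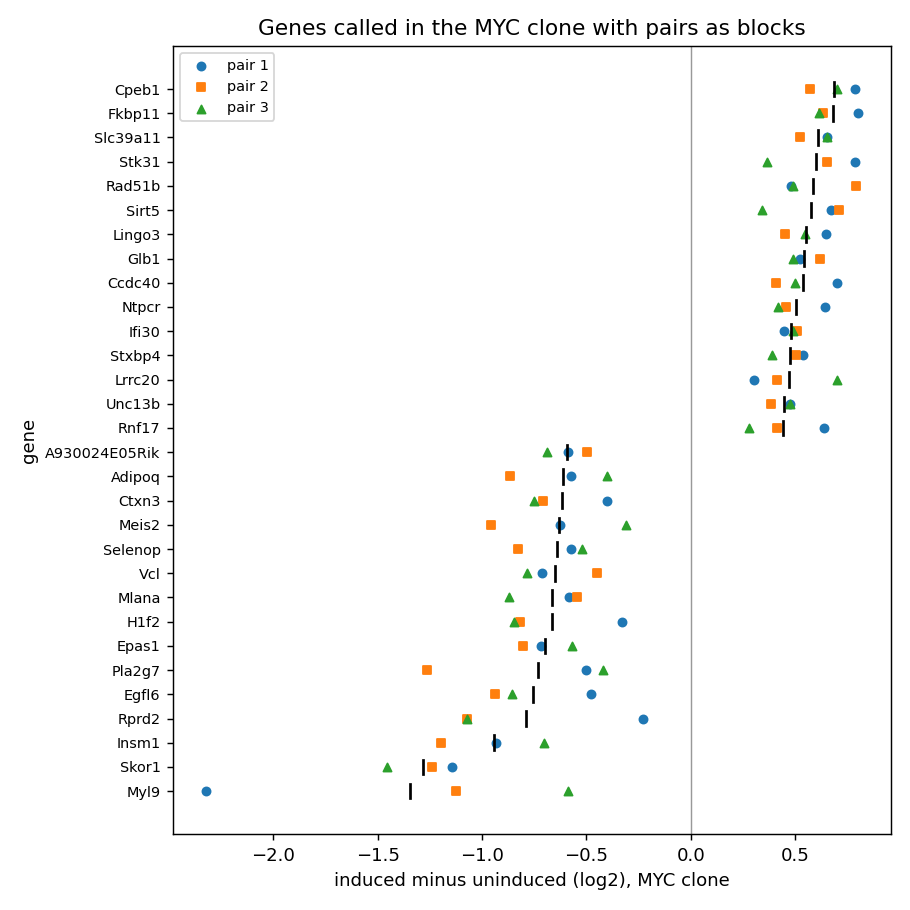
Induced minus uninduced log2 difference of the 3 same-numbered pairs of arrays of the MYC clone, for the 15 highest and 15 lowest genes called with the pairs as blocks; vertical ticks mark the mean of the 3 pairs. Every plotted pair lies on the same side of 0 as its gene's mean, from Myl9 at -1.35 to Cpeb1 at 0.69.

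Genes reported as lowered by MYC had a mean of -0.13 over 30 measured members in the MYC clone, 22 below 0, and did not pass (camera adjusted p = 0.0628), though they did with the block (blocked camera adjusted p = 0.00312, and adjusted p = 0.296 with an estimated correlation). Of the members 0 passed over all genes or adjusted over the list alone, with or without the block. Genes reported in many systems as raised by MYC had a mean of 0.05 over 33 measured members, 21 above 0 (camera adjusted p = 0.0365, and adjusted p = 0.589 with an estimated correlation). The folate enzyme gene Shmt1, at 0.34 (block SE 0.08), and the pyrimidine synthesis gene Umps, at 0.23 (block SE 0.065), rose with the block when adjusted over the list alone, and 0 members rose over all genes. The MYC-raised list also had means of 0.04 in AIREdel, 0.04 in BRWD1, 0.02 in SUMF1, 0.01 in GTF2IRD1 and 0.006 in WBSCR1. It stood at -0.02 in GTF2I and -0.02 in GTF2IRD2. This list was not tested for MYC against the other clones, so its values do not show a rise particular to MYC. Factors of ribosome biogenesis had a mean of 0.07 over 45 measured members in the MYC clone, 35 above 0 (camera adjusted p = 0.00829, and adjusted p = 0.983 with an estimated correlation), with 0 members past either adjustment. Targets of p53 had a mean of -0.13 over 28 members (camera adjusted p = 0.00368, and adjusted p = 0.945 with an estimated correlation). With the block 2 fell when adjusted over the list alone, Pmaip1 at -0.69 (block SE 0.17) and Perp at -0.50 (block SE 0.12), both linked to cell death. Hypoxia and glycolysis genes had a mean of 0.12 over 30 members (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Mxi1, a partner of MAX, at 0.39 (block SE 0.08), rose with the block over all genes and over the list alone. The p53 call ended without uninduced replicate 2 (0.148) or induced replicate 3 (0.203), and the ribosome call without uninduced replicate 1 (0.427) or induced replicate 2 (0.222). The call of the MYC-raised list ended without uninduced replicate 1 (0.213) or 3 (0.0996) or induced replicate 1 (0.144) or 2 (0.206), and the hypoxia call without uninduced replicate 1 (0.178) or 3 (0.125) or induced replicate 2 (0.619), or with only the brighter genes (0.0501).

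In the other 6 clones no gene passed the limma adjusted p after induction, with or without the block over all clones. The counts were 0 in AIREdel (411 genes at an unadjusted p under 0.05), 0 in BRWD1 (291), 0 in GTF2I (340), 0 in GTF2IRD2 (206), 0 in SUMF1 (410) and 0 in WBSCR1 (339). Array weights, estimated from the spread of arrays within groups, gave 59 genes in AIREdel and 11 in WBSCR1. They leaned on single arrays: AIREdel uninduced replicate 1 weighed 5.10, against 0.66 and 0.74 for replicates 2 and 3. WBSCR1 induced replicate 3 weighed 3.365, against 0.76 and 0.295 for replicates 1 and 2. A block in only the clones whose numbers pair gave 1 in BRWD1, and leaving out SUMF1 uninduced replicate 1 gave 3 in SUMF1. On simulated data for the GTF2IRD1 comparison the unblocked test recovered 48 of 50 genes changed 2-fold and 31 of 50 changed 1.41-fold. Those data held changed genes of all simulated sizes at once, which makes the adjusted p easier to pass. Recovery would be lower in a clone with few changed genes, a case that was not simulated.

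Small shifts of gene lists were seen in 5 of these clones, and 0 of the calls held with an estimated correlation after adjustment. AIREdel had lower genes of the integrated stress response, with a mean of -0.16 over 33 measured members and 2 above 0 (camera adjusted p = 1.93e-06, and adjusted p = 0.900 with an estimated correlation). Its largest members, Atf5 at -0.58 (SE 0.205) and Cebpb at -0.46 (SE 0.20), did not pass over all genes or adjusted over the list alone. Sterol synthesis genes had a mean of 0.13 over 20 members in AIREdel (camera adjusted p = 0.0149, and adjusted p = 0.983 with an estimated correlation). Ribosome biogenesis genes had a mean of 0.06 over 45 there (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Of both lists 0 members passed over all genes or adjusted over the list alone. The sterol call ended without AIREdel uninduced replicate 2 (0.686), induced replicate 1 (0.0639) or induced replicate 3 (0.800), and the ribosome call without uninduced replicate 1 (0.232), uninduced replicate 2 (0.0779) or induced replicate 2 (0.413), or with only the brighter genes (0.0779).

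BRWD1 had higher hypoxia and glycolysis genes, with a mean of 0.21 over 30 measured members and 28 above 0 (camera adjusted p = 9.08e-06, and adjusted p = 0.983 with an estimated correlation). The lactate transporter Slc16a3 at 1.33 (block SE 0.425), Egln3 at 0.58 (block SE 0.185), Pfkfb3 at 0.49 (block SE 0.16) and Ankrd37 at 0.46 (block SE 0.14) were the 4 members that rose with the block when adjusted over the list alone, against 0 over all genes. Formative and primed epiblast genes had a mean of 0.13 over 21 members in BRWD1 (camera adjusted p = 0.0391, and adjusted p = 0.945 with an estimated correlation). Pim2, at 0.30 (block SE 0.08), rose with the block when adjusted over the list alone, and 0 members did over all genes. Ribosome biogenesis genes had a mean of 0.05 over 45 (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Lysosome genes had a mean of -0.08 over 33 (camera adjusted p = 0.0175, and adjusted p = 0.983 with an estimated correlation). Of both lists 0 members passed over all genes or adjusted over the list alone. The epiblast call ended without BRWD1 uninduced replicate 2 (0.230) or 3 (0.434) or induced replicate 1 (0.280) or 2 (0.117). The ribosome call ended without uninduced replicate 2 (0.739) or 3 (0.842) or induced replicate 1 (0.496), and the lysosome call without uninduced replicate 3 (0.494) or induced replicate 1 (0.614).

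In GTF2I the integrated stress response had a mean of -0.11 over 33 measured members (camera adjusted p = 0.0139, and adjusted p = 0.983 with an estimated correlation). In GTF2IRD2 it had a mean of -0.09 (camera adjusted p = 0.0139, and adjusted p = 0.983 with an estimated correlation). In both clones 0 members passed over all genes or adjusted over the list alone. Heat shock genes in GTF2IRD2 had a mean of 0.10 over 21 members (camera adjusted p = 0.0458, and adjusted p = 0.983 with an estimated correlation). The inducible chaperone genes Hspa1b at 0.93 (block SE 0.25) and Hspa1a at 0.79 (block SE 0.22) rose with the block when adjusted over the list alone, against 0 over all genes. Sterol synthesis genes in GTF2IRD2 had a mean of 0.08 over 20 members (camera adjusted p = 0.0499, and adjusted p = 0.983 with an estimated correlation). In SUMF1, genes of the unfolded protein response had a mean of 0.10 over 28 members, 24 above 0 (camera adjusted p = 0.0112, and adjusted p = 0.589 with an estimated correlation). The disulfide isomerase gene Pdia3, at 0.75 (SE 0.24), did not pass over all genes or adjusted over the list alone. Sulfatase genes, whose products SUMF1 activates, had a mean of 0.04 over 12 measured members in this clone, 9 above 0, and did not pass (camera adjusted p = 0.667). Calls ended in GTF2I without uninduced replicate 1 (0.556) or 3 (0.0913) or induced replicate 2 (0.338) or 3 (0.0950), and in SUMF1 without uninduced replicate 1 (0.170) or induced replicate 2 (0.261). In GTF2IRD2 the stress call ended without uninduced replicate 3 (0.365) or induced replicate 1 (0.201) or 2 (0.0661). The sterol call ended without 4 of the 6 arrays (up to 0.521 without uninduced replicate 1) and the heat shock call without 5 of the 6 (up to 0.306 without uninduced replicate 2) or with only the brighter genes (0.0681).

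The mean induction effect over the 8 clones asked what tetracycline withdrawal and induction had in common. Hypoxia and glycolysis genes had a mean of 0.09 over 30 measured members, 27 of them above 0 (camera adjusted p = 2.38e-07, and adjusted p = 0.945 with an estimated correlation). With the block, 12 members rose when adjusted over the list alone, against 0 over all genes, among them the hypoxia-responsive genes Egln3 at 0.36 (block SE 0.07), Ankrd37 at 0.285 (block SE 0.05), Bnip3 at 0.25 (block SE 0.05) and Pfkfb3 at 0.24 (block SE 0.06). Integrated stress response genes had a mean of -0.07 over 33 members, 5 above 0 (camera adjusted p = 3.37e-07, and adjusted p = 0.770 with an estimated correlation). With the block 5 fell when adjusted over the list alone, against 0 over all genes, including Nupr1 at -0.20 (block SE 0.06), Chac1 at -0.19 (block SE 0.06), Cebpb at -0.18 (block SE 0.05) and Trib3 at -0.15 (block SE 0.04). Sterol synthesis genes had a mean of 0.05 over 20 members (camera adjusted p = 0.00427, and adjusted p = 0.983 with an estimated correlation). With the block 3 rose when adjusted over the list alone, against 0 over all genes: Cyp51 at 0.125 (block SE 0.03), Sqle at 0.09 (block SE 0.03) and Msmo1 at 0.09 (block SE 0.03). Taken gene by gene over 18194 genes, 0 passed the limma adjusted p without or with the block over all clones (372 and 1018 genes at an unadjusted p under 0.05). A block in only the 6 clones whose numbers pair called 3 in that alternative: Ankrd37 at 0.285 (adjusted p = 0.0183) and the transferrin receptor gene Tfrc at 0.17 (adjusted p = 0.0122) rose, and Gtf2ird1 at -0.24 (adjusted p = 0.0183) fell. The Gtf2ird1 value came mostly from the GTF2IRD1 clone, at -1.61: it was positive in 3 of 8 clones (exact sign-flip p = 0.117), and the mean of the other 7 was -0.05.

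Smaller mean shifts over the 8 clones were those of ribosome biogenesis genes at 0.03 over 45 members (camera adjusted p = 0.00829, and adjusted p = 0.983 with an estimated correlation). Replication and G1-S genes had a mean of 0.03 over 28 (camera adjusted p = 0.0383, and adjusted p = 0.983 with an estimated correlation), and unfolded protein response genes 0.03 over 28 (camera adjusted p = 0.0365, and adjusted p = 0.770 with an estimated correlation). Of these 3 lists, 0 members passed over all genes or adjusted over the list alone. Without the block, the fixed lists held few members past the test after induction when adjusted over the list alone: Mixl1 fell in SUMF1 (-0.395) and in the mean (-0.12). Plac1 rose in SUMF1 (0.40), Lum in WBSCR1 (0.36) and Tfrc in BRWD1 (0.45) and the mean (0.17), and Gtf2ird1 fell in GTF2IRD1 and the mean. Leaving out 1 array ended the ribosome call in 8 cases (up to 0.197 without BRWD1 induced replicate 1) and the G1-S call in 21 (up to 0.490 without GTF2I induced replicate 1). It ended the unfolded protein call in 17 (up to 0.0970 without BRWD1 induced replicate 3) and the sterol call without AIREdel uninduced replicate 2 (0.0978) or SUMF1 uninduced replicate 2 (0.115). With only the brighter genes the G1-S (0.154) and unfolded protein (0.140) calls ended. Taking each clone's list mean as 1 value, the exact sign-flip p was 0.0156 for the hypoxia list, positive in 7 of 8 clones, and 0.0234 for the stress list, positive in 1 of 8. The exact sign-flip p was also under 0.05 for the heat shock (0.0234), G1-S (0.03125) and sterol synthesis (0.0469) lists. After adjustment over the 27 lists these exact p-values were 0.211, or 0.253 for sterol synthesis.

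**Figure D3:**
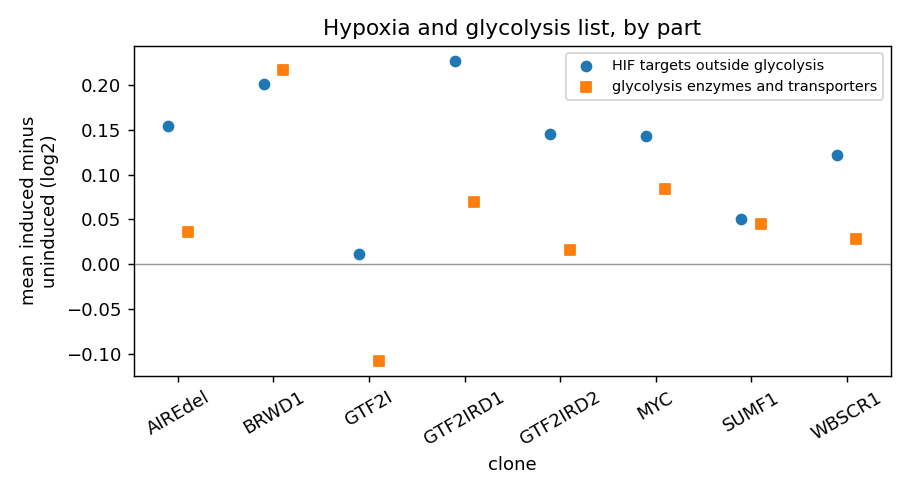
Mean induced minus uninduced log2 difference by clone for the 16 measured targets of hypoxia-inducible factor outside glycolysis (circles) and the 14 measured enzymes and transporters of glycolysis (squares) of the hypoxia and glycolysis list. The first part lies above 0 in 8 of 8 clones, the second in 7 of 8.

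Setting each clone against the mean of the other 7 asked what was particular to it. For MYC, induced for 17 h against 24 h in the others, the clone and the time cannot be told apart. Gtf2ird1 at -1.56 (SE 0.14, limma adjusted p = 5.25e-10) and Ttc32 at -1.75 (SE 0.15, limma adjusted p = 2.27e-10) fell in GTF2IRD1 relative to the rest, and no gene passed in another clone. With the block, GTF2IRD1 had 6 genes, with Cdc42ep2 at 0.65 higher and Trps1 at -0.75, Eprn at -0.73 and Mcf2 at -0.56 lower besides the first pair. With the block, MYC had 40 genes, 9 higher and 31 lower, led by Myl9 at -1.30, Skor1 at -1.25, Insm1 at -1.08, the endocrine regulator Neurog3 at -0.95 (4.63 when induced, so also of uncertain size) and Car3 at -0.93. The 5 largest of the 9 rises were those of the dim Cpeb1 at 0.74, Fkbp11 at 0.66, Slc39a11 at 0.65, Rad51b at 0.60 and Glb1 at 0.53. The MYC count fell to 8 with a block in only the 6 clones whose numbers pair, and to 11, 1 or 2 without MYC pair 1, 2 or 3, and the GTF2IRD1 count to 3, 3 or 2 without its pairs. The counts without the block were 0 in AIREdel (349 at an unadjusted p under 0.05), BRWD1 (395), GTF2I (361), GTF2IRD2 (184), MYC (524), SUMF1 (385) and WBSCR1 (306). Over the 28 pairs of clones the correlation of their responses across genes averaged 0.0173, from -0.226 to 0.245, and over the 3 pairs of GTF2I family clones 0.00511. Over the brighter genes it averaged 0.0403, from -0.396 for BRWD1 with GTF2I to 0.423 for GTF2IRD2 with WBSCR1, and 0.125 over the 6 pairs of Williams region clones. Genes are not independent replicates, and no p-value is given.

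The uninduced clones differed far more from EB3 than from their induced cells. The immediate early genes Jun, at -2.18 (SE 0.25), and Egr1, at -1.95 (SE 0.40), fell in the mean of the 8 uninduced clones. So did Pdcl2 at -2.70 (SE 0.47), Serinc5 at -2.25 (SE 0.36), Pdlim4 at -2.12 (SE 0.24), the acetyl-CoA synthetase gene Acss1 at -2.05, Dner at -1.88, Lrrc31 at -1.77, Rab3il1 at -1.75 and Clybl at -1.67. Among the rises were Skor1 at 1.94 (SE 0.28), the zinc finger gene Zfp423 at 1.86 (SE 0.22), titin (Ttn) at 1.77 (SE 0.27), the LIF-responsive signalling inhibitor Socs3 at 1.70 (SE 0.26, and 2.55 without EB3 replicate 3), Septin1 at 1.59, Exoc3l at 1.55, Ier3 at 1.41 and the homeobox gene Gbx2 at 1.38. The EB3 arrays overlapped with those of the clones for Socs3, at an SD of 1.47, and for Exoc3l, Ier3, Gbx2, Serinc5, Jun, Acss1, Egr1 and Rab3il1. Sizes are uncertain where 1 side lay below the median array level of 5.11: Skor1 (3.48 in EB3), and Pdcl2 (4.43), Serinc5 (4.39), Dner (4.38) and Lrrc31 (4.88) in the clones. In all, 3973 genes passed the limma adjusted p, 1777 higher and 2196 lower, and 842 of them differed by at least 1.5-fold. The count was 1827 without EB3 replicate 1 and 1989 without EB3 replicate 2. All 8 clones lay nearer to EB3 replicate 3 than to the other two, by -0.03 to -0.06 in mean absolute log2 difference.

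**Figure D4:**
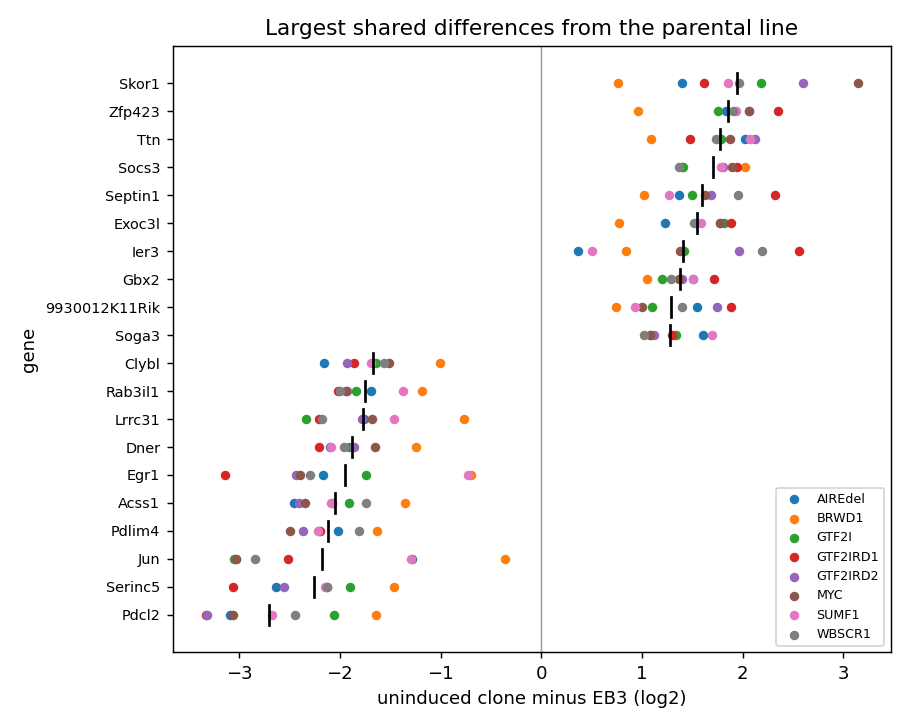
Uninduced clone minus EB3 log2 difference of the 10 highest and 10 lowest genes of the mean over the 8 clones, with 1 point per clone and a tick for the mean. The genes were chosen for 1 sign in all 8 clones, which share the 3 EB3 arrays, and run from Pdcl2 with a mean of -2.70 to Skor1 with 1.94.

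Lysosomal genes were lower in the uninduced clones as a group, with a mean of -0.38 over 33 measured members, of which 21 fell and 1 rose, the lysosomal regulator Tfeb at 0.42. These counts were 24 and 1 adjusted over the list alone (camera adjusted p = 1.50e-09, and adjusted p = 0.389 with an estimated correlation). Examples were Hexa at -1.38 (SE 0.21), Lamp2 at -1.09 (SE 0.13), Neu1 at -0.82 (SE 0.125) and Glb1 at -0.81 (SE 0.14). Sterol synthesis genes had a mean of -0.42 over 20 members, with 11 fallen and 0 risen (14 and 0 adjusted over the list alone; camera adjusted p = 1.73e-06, and adjusted p = 0.975 with an estimated correlation). They were led by Insig1 at -0.94 (SE 0.19) and Cyp51 at -0.87 (SE 0.14). Genes reported as lowered by MYC had a mean of -0.23 over 30 members, 11 fallen and 1 risen (11 and 4 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.589 with an estimated correlation). Among them were Ccn2 at -1.28 (SE 0.29), Ndrg2 at -1.26 (SE 0.23) and Btg1 at -0.93 (SE 0.12). Hypoxia and glycolysis genes had a mean of -0.25 over 30 members, 11 fallen and 1 risen (12 and 1 adjusted over the list alone; camera adjusted p = 0.00829, and adjusted p = 0.983 with an estimated correlation). The falls were led by Bnip3 at -1.07 (SE 0.30) and P4ha1 at -1.01 (SE 0.22). The Bnip3 call ended without EB3 replicate 1 (0.0788) or 2 (0.0869). Targets of p53 had a mean of -0.15 over 28 members, 8 fallen and 0 risen over all genes and adjusted over the list alone (camera adjusted p = 0.0365, and adjusted p = 0.983 with an estimated correlation). Among them were Trp53inp1 at -0.65 (SE 0.12) and Mdm2 at -0.52 (SE 0.11). The p53 call ended without EB3 replicate 3 (0.279), BRWD1 uninduced replicate 3 (0.0521) or WBSCR1 uninduced replicate 2 (0.0553). With only the brighter genes, the calls of the MYC-lowered (0.215), hypoxia (0.0608) and p53 (0.156) lists ended.

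Marker lists of cell states did not pass the camera test against EB3, though single members passed the test of genes. Over all 18194 genes 3973 passed in this comparison, 1777 higher and 2196 lower, so some members would pass in most lists. The member counts below were not tested against that share and do not by themselves show a change of a list. Of 28 naive pluripotency genes 11 fell and 5 rose (14 and 5 adjusted over the list alone, camera adjusted p = 0.0662), with Klf2 at -0.65 and Fgf4 at -0.54 lower and Socs3 at 1.70 higher. Of 21 formative and primed epiblast genes 6 fell and 3 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.578). The Nodal inhibitor gene Lefty1, at -1.63, and Zic5, at -1.36, fell. Of 24 primitive streak and mesoderm genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0926). Of 29 primitive and visceral endoderm genes 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.519). Of 24 neuroectoderm genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.545), with Gbx2 at 1.38 and Map2 at -1.17. Of 23 trophectoderm genes 7 fell and 1 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.135), with Krt7 at -1.55. Of 26 fibroblast and feeder genes 6 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.403), with Ccn1 at -1.55. Of 10 genes of the 2-cell-like state 1 fell over all genes and 0 adjusted over the list alone (camera adjusted p = 0.895).

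The remaining lists did not pass against EB3 either, and their member counts are to be read against the same share of all genes. Ribosome biogenesis had 7 of 45 members risen and 0 fallen (7 and 0 adjusted over the list alone, camera adjusted p = 0.234), with Imp4 at 0.57. The MYC-raised list had 5 of 33 risen and 0 fallen (4 and 0 adjusted over the list alone, camera adjusted p = 0.684). G1-S genes had 3 risen and 3 fallen of 28 (the same counts adjusted over the list alone, camera adjusted p = 0.667). Mitotic genes had 3 risen and 5 fallen of 31 (the same counts adjusted over the list alone, camera adjusted p = 0.595). The unfolded protein response had 0 risen and 5 fallen of 28 (the same adjusted over the list alone, camera adjusted p = 0.667), with Dnajb9 at -0.73. The integrated stress response had 2 risen and 0 fallen of 33 (the same adjusted over the list alone, camera adjusted p = 0.726). Heat shock genes had 4 risen and 2 fallen of 21 (the same adjusted over the list alone, camera adjusted p = 0.557), with Hspa1b at 1.00. Interferon response genes had 4 risen and 2 fallen of 28 (the same adjusted over the list alone, camera adjusted p = 0.667), with the RNA sensor gene Ddx58 at 1.17 and B2m at -0.94. Sulfatases had 0 risen and 2 fallen of 12 (0 and 1 adjusted over the list alone, camera adjusted p = 0.997). Antigen genes dependent on AIRE had 2 risen and 2 fallen of 26 (1 and 2 adjusted over the list alone, camera adjusted p = 0.281). Reported targets of the TFII-I family had 2 risen and 4 fallen of 24 (4 and 4 adjusted over the list alone, camera adjusted p = 0.850). Genes of the Williams region had 1 risen and 4 fallen of 24 (the same adjusted over the list alone, camera adjusted p = 0.667). Translation initiation genes had 2 risen and 3 fallen of 24 (the same adjusted over the list alone, camera adjusted p = 0.547). Histones with chromatin readers had 1 risen and 0 fallen of 18 (the same adjusted over the list alone, camera adjusted p = 0.667).

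Taken clone by clone, the uninduced cells differed from EB3 in 3723 genes in GTF2IRD2, 3364 in GTF2IRD1, 3340 in GTF2I, 3218 in MYC, 3026 in WBSCR1, 1982 in SUMF1, 1845 in AIREdel and 68 in BRWD1. In SUMF1, the endocytic receptor genes Cubn at 3.59 (SE 0.55) and Amn at 2.40 (SE 0.38), and Dab2 at 2.81 (SE 0.41) rose. The transcription factor gene Gata6 at 2.39 (SE 0.33) and the basement membrane collagen Col4a2 at 2.27 (SE 0.45) rose too, and Lefty1 fell, at -2.17 (SE 0.39). Gata6 lay above EB3 in 8 of 8 clones, Cubn, Amn and Col4a2 in 3 and Dab2 in 1, and no test set SUMF1 against the other clones here. At an EB3 level of 4.94 the size of the Gata6 value is uncertain. The nuclear RNA Malat1 rose by 3.28 (SE 0.46) in MYC and 3.25 (SE 0.46) in GTF2IRD2, and the neural regulator Pax6 by 2.60 (SE 0.44) and the cyclin gene Ccnd2 by 2.18 (SE 0.43) in MYC. Without MYC uninduced replicate 1, Pax6 stood at 1.83 and Ccnd2 at 1.57, and without replicate 3 Pax6 stood at 3.29. Jun fell in GTF2I (-3.05), MYC (-3.04), GTF2IRD2 (-3.03), WBSCR1 (-2.84) and GTF2IRD1 (-2.51), and Egr1 in GTF2IRD1 (-3.14). In AIREdel, Ttn rose by 2.02 and Pdcl2, dim in the clone at 4.04, fell by 3.09. In BRWD1, Socs3 rose by 2.02 (SE 0.34), or 2.87 without EB3 replicate 3, and Pdlim4, at -1.64 (SE 0.33), and Cpeb1, at -1.17 (SE 0.13) and dim on both sides, fell. The BRWD1 count was 6 without EB3 replicate 1, 4 without EB3 replicate 2 and 262 without EB3 replicate 3, and the calls of Socs3 (0.110 and 0.0926) and Pdlim4 (0.216 and 0.102) ended without EB3 replicate 1 or 2. The Pdlim4 call also ended without BRWD1 uninduced replicate 2 (0.0807) or 3 (0.0625), and the count was then 13 or 27. Without EB3 replicate 1 the counts were 678 in AIREdel, 836 in SUMF1, 1771 in WBSCR1, 1959 in GTF2I, 2018 in MYC, 2082 in GTF2IRD1 and 2262 in GTF2IRD2. Without EB3 replicate 2 they were 734 in AIREdel, 916 in SUMF1, 1602 in WBSCR1, 1879 in GTF2I and 2037 in GTF2IRD1. Uninduced arrays mattered as well: AIREdel had 1071 or 629 genes without its replicate 1 or 2, GTF2I 1961 and SUMF1 966 without their replicate 2, and WBSCR1 1813 or 2010 without its replicate 1 or 3. The BRWD1 split of 11 higher and 57 lower became 10 and 131 when each array was centred on its median.

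The differences from EB3 correlated between clones at a mean r of 0.72 across genes, from 0.53 to 0.89. All 8 comparisons share the 3 EB3 arrays, and unchanged clones simulated against shared controls gave 0.50. The mean covariance was 0.0756, against a simulated 0.0128.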

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

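The tests of another Gtf2ird1 probe set, of tetracycline removal for both the GTF2IRD1 and the MYC genes, of fibroblast genes and of culture or array batches were chosen only after the result was seen. The serum response factor list and the split by whole lines were written after the results they examine were seen but before their own tests.

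The response of GTF2IRD1 differed from the mean of the other 7 clones by -1.559 for Gtf2ird1 and -1.747 for Ttc32, and with the block 6 genes differed in GTF2IRD1 and 40 in MYC, which is why these results were examined further. Probe sets with no gene symbol or with several were outside the comparisons. Of 10092 such probe sets, 2 passed the blocked adjusted p in GTF2IRD1, 6 in MYC and 3 in AIREdel, whose numbers do not pair (lowest blocked adjusted p = 0.0282), with 0 in these clones by limma without the block.

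In GTF2IRD1, all 3 induced arrays lay below all uninduced ones for Gtf2ird1 and Ttc32. Another Gtf2ird1 probe set also differed, by -0.694 (SE 0.142), which argues against 1 misreading probe set for the fall within the clone. The 2 probe sets differ on the level relative to EB3. The other one went from 7.49 uninduced to 6.80 induced, near its EB3 level of 6.89. The tested one went from 9.36 to 7.75, below its EB3 level of 9.67. Removal of tetracycline alone does not account for it, since the mean difference of the other 7 clones was -0.04865 for Gtf2ird1 and 0.0106 for Ttc32. Wdr35, next to Ttc32 in the gene table, differed by 0.00582 (SE 0.157), which argues against a shared promoter region. A response to the induced factor, or an event particular to this clone, may explain the falls, and neither was tested.

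In MYC, Vcl, Myl9, Cald1 and Lpp, grouped only after their values were seen, were lower with the block. A loss of fibroblasts stays open. The 6 list members above the median gene lay lower, at -0.2249 (SE over the 6 genes 0.0525). However, 3 of them are also targets of serum response factor, and Col1a1, Col1a2 and Col3a1, at 4.02, 4.73 and 2.46, were too dim to decide. The means of the other 7 clones were -0.005631 over Vcl and Myl9 and -0.03618 over Cald1 and Lpp. These argue against an effect of tetracycline removal still present at 24 h. They cannot decide on an earlier, passing one, as the MYC clone was read at 17 h and the others at 24 h. Subtracting the other 7 took Cald1 from -0.57 (block SE 0.12) to -0.50 (0.13) and Lpp from -0.56 (0.11) to -0.55 (0.12). Their calls then ended (blocked limma adjusted p = 0.112 and 0.0538), with 40 genes passing instead of 65. Differences, SE and the number of genes passing all moved, and their shares in this were not tested. A wider fall of genes driven by serum response factor may be present. The 31 further targets had a mean of -0.1813 (SE over the 31 genes 0.0308), 27 below 0 and 0 called singly. The fry p was 8.44e-04, and 0.00327 against the other 7 clones. The list was written because Vcl, Myl9, Cald1 and Lpp were low in these same arrays. Genes that vary with them across arrays would then be low too, so these p-values are not independent support. An SE over genes treats genes as independent and does not measure the spread of arrays.

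Between the uninduced clones and EB3, 3973 genes differed in the mean. The count was 1827 without EB3 replicate 1, below 0.5 of the full count, and 1989 without EB3 replicate 2, just above it. By the rule set beforehand an EB3 array that stands apart may account for part of this, but fewer controls also lower the power. The EB3 array nearest to the clones and of lowest array weight was replicate 3 (0.637, against 1.662 and 1.108). Its loss left the count within 1.5 times, so the drops without replicate 1 or 2 do not show that 1 such array made the calls. A shift of level or spread left by normalization is argued against by 3763 genes, the lower count after quantile normalization or centring. Batches of culture or arrays cannot be told apart from the groups, since the labels give none: BRWD1 and AIREdel lay nearer to EB3 replicate 3 by -0.0425, as did all 8 clones. The derivation of the clones is an open biological difference and was not tested.

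Other splits of the same arrays were counted for each result. For single clones the 10 splits of 6 arrays, and the 4 exchanges within pairs, are too few for a share under 0.05. A real count of 0 is met by every split, so these cases test nothing. After induction, 10 of 10 splits gave as many genes as the real 0 in AIREdel (highest other 2), BRWD1 (1), GTF2I (378), GTF2IRD2 (2), MYC (990), SUMF1 (36) and WBSCR1 (37), and 3 of 10 did in GTF2IRD1 (2 real, highest other 4). Against the other 7 clones, 10 of 10 did in AIREdel (highest other 1), BRWD1 (0), GTF2I (255), GTF2IRD2 (0), MYC (725), SUMF1 (4) and WBSCR1 (8), and 2 of 10 in GTF2IRD1 (2 real, highest other 4). Splits that call many genes in MYC and GTF2I point to a structure of the samples. In MYC the 4 splits with 459 to 990 genes keep the arrays numbered 1 together, and the 3 that part every pair, as the real one does, gave 0. In GTF2I the split with 378 parts every pair, so pairing does not account for it. With the block, 1 of 4 exchanges gave as many: 65 in MYC (highest other 0), 40 for MYC against the other 7 (1), 13 in GTF2IRD1 (0) and 6 for GTF2IRD1 against the other 7 (0).

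Against EB3, 1 of 10 splits gave as many genes in each clone: AIREdel 1845 (highest other 8), BRWD1 68 (8), GTF2I 3340 (247), GTF2IRD1 3364 (10), GTF2IRD2 3723 (6), MYC 3218 (296), SUMF1 1982 (31) and WBSCR1 3026 (191). For the mean against EB3, 1 of 100 drawn splits gave as many as 3973 (highest other 999), the smallest share that 100 draws allow. These draws mix the lines within groups, which widens the spread and lowers the counts, so they do not exclude chance between lines. Each line was therefore also set against the other 8. Of such splits 1 of 9 gave as many as 3973 (highest other 1820, for MYC), and 9 are too few for a share under 0.05. For the mean induction effect 100 of 100 draws gave as many as the real 0 (highest other 3), which a count of 0 fixes in advance.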

How the results depend on the processing

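The block in only the 6 clones whose numbers pair, the induced arrays against EB3, the block combined with other alternatives, and the similarity and targeted gene counts were chosen after seeing the data. Where counts moved, the cause was not tested, except that a 1.5-fold threshold can only lower a count and that leaving out arrays or using fewer lowers the power. Array weights gave 59 genes after induction in AIREdel, 11 in GTF2IRD1, 11 in WBSCR1 and 1 in the mean. They gave 21 for AIREdel and 7 for GTF2IRD1 against the other 7 clones, and, against EB3, 5598 in AIREdel, 2230 in BRWD1, 5689 in GTF2IRD1, 6453 in GTF2IRD2, 2990 in SUMF1, 5541 in WBSCR1 and 6171 in the mean. The AIREdel counts lean on uninduced replicate 1, at a weight of 5.10 against 0.66 and 0.74 for replicates 2 and 3. The replicate block gave 13 in GTF2IRD1 and 65 in MYC, 6 and 40 against the other 7, and 41 list calls in the induction comparisons, among them the 26 made without it, and 0 of the 41 held with an estimated correlation. It left the other counts after induction at 0 and those against EB3 within 1.5 times, such as 4145 in the mean. With a block in only the 6 pairing clones the counts were 1 in BRWD1, 7 in GTF2IRD1, 13 in MYC and 3 in the mean, and 5 and 8 for GTF2IRD1 and MYC against the other 7. The compared arrays alone gave 5 in GTF2IRD1 and, against EB3, 34 in BRWD1, 1594 in GTF2I, 1658 in MYC, 1135 in SUMF1 and 1846 in WBSCR1. The filter on dim genes gave 1 gene in the mean induction effect, 38 in BRWD1 and 1992 in WBSCR1 against EB3, and quantile normalization 1 in the mean induction effect. For BRWD1 against EB3, median centring gave 141, every named probe set 128 and the induced arrays 264. With a 1.5-fold threshold the counts against EB3 were 764 in AIREdel, 45 in BRWD1, 1263 in GTF2I, 1295 in GTF2IRD1, 1473 in GTF2IRD2, 1428 in MYC, 901 in SUMF1, 1087 in WBSCR1 and 842 in the mean. List calls numbered 0 with an estimated correlation and 5 with fry, and the mean similarity of clones was -0.1405 after subtracting the mean of the others, which by itself makes unrelated clones correlate below 0.

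With the block, the MYC count of 65 was 85 with the dim filter, 43 with array weights and 49 with every named probe set, and 21, 1 or 6 without pair 1, 2 or 3. The GTF2IRD1 count of 13 was 84 with array weights and 5, 4 or 6 without pair 1, 2 or 3.

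Leaving out 1 array gave, after induction, 0 to 0 genes in AIREdel, BRWD1, GTF2I, GTF2IRD2 and WBSCR1, 2 to 4 in GTF2IRD1 (4 without induced replicate 2), 0 to 2 in MYC (2 without uninduced replicate 1), 0 to 3 in SUMF1 (3 without uninduced replicate 1) and 0 to 1 in the mean. Against the other 7 clones it gave 0 to 1 in AIREdel and MYC, 2 to 3 in GTF2IRD1 and 0 to 0 in the others. Against EB3 it gave 629 (AIREdel uninduced replicate 2) to 2044 in AIREdel, 4 (EB3 replicate 2) to 262 (EB3 replicate 3) in BRWD1, 1879 (EB3 replicate 2) to 3316 in GTF2I, 2037 (EB3 replicate 2) to 3129 in GTF2IRD1, 2262 (EB3 replicate 1) to 3362 in GTF2IRD2. It gave 2018 (EB3 replicate 1) to 3151 in MYC, 836 (EB3 replicate 1) to 2307 in SUMF1, 1602 (EB3 replicate 2) to 2939 in WBSCR1 and 1827 (EB3 replicate 1) to 4163 in the mean. List calls ranged from 24 to 37, the similarity from 0.00491 to 0.02968, and the targeted genes past the adjusted p from 1 to 1.

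Taking the probe set of lowest adjusted p reversed 2 targeted genes against EB3: Gtf2ird1 in GTF2IRD1, at -0.31, became 0.6021 (adjusted p = 0.00287), and Eif4h in WBSCR1, at -0.14, became 0.654 (adjusted p = 0.00126). The Eif4h probe sets went both ways. The one at 0.654 lay at only 5.33 in EB3. Another, at 4.09 in EB3, stood at -0.65 and passed too, and the rest stood at -0.09, -0.04 and 0.23. List results reversed without 1 array: cholesterol synthesis in AIREdel induced minus uninduced without uninduced replicate 2 (0.686), ribosome biogenesis in BRWD1 induced minus uninduced without induced replicate 1 (0.496), and hypoxia and glycolysis in GTF2IRD1 induced minus uninduced without uninduced replicate 2 (0.0568) or induced replicate 1 (0.802). The adjusted p of these 3 ranged, over the arrays left out, from 4.29e-07 to 0.800, from 7.50e-08 to 0.842 and from 4.86e-11 to 0.802. Of the 31 list calls, 8 outlasted the loss of each array, and 6 of these also the dim filter. Of 294 values of named genes 190 stayed on the same side in the same direction throughout, and of 123 called ones 24 lost the call at least once. Median shifts of all genes between scalings stayed below 0.1 log2. Low signal limits dim genes most, as in the Ttc32 probe set with a mean level of 4.90.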

Other observations

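The test of parts of the hypoxia list was written after the whole list was seen to be higher, and before the parts were measured. A hypothesis was that glycolysis enzymes carry the rise of hypoxia and glycolysis genes after tetracycline removal. The 16 targets of hypoxia-inducible factor outside glycolysis had a mean of 0.1319 over the clones (SD 0.0717), above 0 in 8 of 8 (exact sign-flip p = 0.00781, the smallest possible), which argues against it. The 14 glycolysis enzymes and transporters had a mean of 0.0484, above 0 in 7 of 8 clones (exact sign-flip p = 0.164). Whether a common factor such as medium change or culture density underlies this was not tested, since no parental cells without tetracycline were profiled.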
